A study of Arabidopsis thaliana with 6 samples.

How the data were processed

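Samples were total RNA from leaf pools of Arabidopsis thaliana, labelled from 6 µg with a one-cycle 3' amplification kit per the labels' protocols and hybridised to Affymetrix arrays, 1 array per pool. Groups and replicate numbers were taken from the labels: 2 control, 2 local and 2 systemic arrays, which the labels call biological replicates. The deposited values are log2 expression values per probe set, which the authors made with RMA, and Affymetrix Expression Console is also named, both per the submitters' processing notes, which give no version. RMA corrects background, sets all arrays to the same distribution and summarises the probes of a set. The arrays are therefore compared relative to each other, a change of all transcripts in one direction would not be seen, and differences of dim probe sets are compressed. Quartiles were nearly the same on all arrays (medians 6.22 to 6.29), as such scaling leaves them. The table has no detection calls, so dim values could not be told from background. Scanner files were not used here.

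The table held 22810 probe sets. The 64 control probe sets were left out and the other 22746 were tested without a filter on dim signals. Genes were named from the platform annotation given for the table, updated through Entrez numbers or locus tags with a gene table of the TAIR10.1 assembly: 13513 probe sets had 1 listed gene, 503 several and 8730 none listed, and the last are unnamed here. Of those with 1 gene, 13436 were matched through the Entrez number, 48 through the locus, and 29 kept the platform's name. No gene was named from a probe set with several. Coordinates are not given, and the order of genes along the chromosomes was taken from the TAIR10.1 gene table. Of the called probe sets, 52.5% in local against control, 50.8% in systemic against control and 52.8% in local against systemic have 1 listed gene. Tests of upstream motifs and of gene structure were planned but not run, since no genome was used here.

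Differences were fitted with limma 3.58.1 in R 4.3.3, with a mean per group and all 6 arrays sharing one estimate of the spread (3 residual and 4.85 prior degrees of freedom), two-sided, without a replicate block. P-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05, and a second count required an absolute log2 difference of at least 1. Standard errors are the moderated ones of the model. With 2 arrays against 2, non-overlapping groups arise by chance in 33.3% of probe sets, and 59.3%, 50.7% and 53.4% of probe sets had them in the 3 comparisons (local against control, systemic against control, local against systemic).

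Named genes were chosen by a rule fixed before the data were examined: for local and for systemic against control, the 15 largest rises and 10 largest falls among probe sets with 1 gene, an adjusted p under 0.05 and both replicates apart, 1 per gene, 8 in each direction for local against systemic, and the 4 members with the smallest p of each described list. Lists of pathway genes and cell type markers, 30 in number with 344 members, were fixed at the same time. Of the members, 40 had a probe set of their own named here. The 12 lists without any were not analysed here, 12 lists with 1 or 2 are given as values, and 6 lists with at least 3 were tested with limma's camera (preset correlation 0.01), the minimum of 3 being set after the data were seen. The probe set with the highest mean over all arrays stood for its gene. After the fixed lists had lost most of their members, families of genes that share a symbol stem and have at least 5 measured members (45 families) were tested the same way, a choice made after seeing the data.

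The fit was tested on simulated data with the means and spreads of these arrays and 200 changed probe sets per draw, 50 per size, over 20 draws of 22746 probe sets. In the simulated local comparison 45.1% of changes of 0.5 (log2) were recovered, 99.1% of changes of 1, and 100% of changes of 2. In the simulated systemic comparison 46.2% of changes of 0.5 and 98.7% of changes of 1 were recovered. False calls made up 8.92% and 9.83% of the calls, more than the nominal share. The overlap of calls was set beside 100 simulations of unchanged groups against the same control arrays.

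Alternatives fixed before the data were examined were the replicate number as a block, median centring, cyclic loess, filters on dim probe sets at the 25th percentile and the median, trended and robust variance moderation, the 4 arrays of the groups compared, only probe sets with 1 gene, each array left out in turn, and for lists an estimated correlation, fry and the mean of a gene's probe sets. Camera compares a list with the other genes, while fry tests it against no change, so the 2 answer different questions. With an estimated correlation camera also rests on the 3 residual degrees of freedom. A list can then fail without any correlation among its members. Where an array left out leaves a group with a single array, that array is assumed to vary like the other groups.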

Results

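Transcript levels were measured with Affymetrix expression arrays in rosette leaves of Arabidopsis thaliana, ecotype Columbia, 10 min after mechanical wounding. In 5-week-old plants, 3 rosette leaves were wounded by closing tweezers over the midvein. The 3 groups were control leaves from unwounded plants, local leaves (the wounded leaves themselves) and systemic leaves (unwounded leaves of wounded plants). Each group had 2 biological replicates, and each replicate was a pool of leaves from 3 plants, so that 6 arrays were compared. Their number limits the precision of each value. Levels are log2 RMA values. The replicate arrays correlated across probe sets at r = 0.995 in control, 0.997 in local and 0.996 in systemic leaves, and the median SD between the replicates of a probe set was 0.0850, 0.0770 and 0.0780. The first principal component held 71.8% of the variance and placed the control arrays at -42.0 and -42.7, the systemic arrays at 4.15 and -7.94, and the local arrays at 46.8 and 41.7. The 3' minus 5' difference of the ubiquitin control probe sets, a sign of RNA quality, was 0.97 and 1.05 on the local arrays, below 1.33 and 1.25 on the control and 1.23 and 1.26 on the systemic arrays, while those of actin and GAPDH overlapped between control and local arrays. The means of the poly-A and hybridization spikes were lowest on control replicate 2 (7.40 and 9.41, against 7.73 to 8.52 and 9.79 to 9.97 on the other arrays).

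The comparison of local with control leaves addressed the response of the wounded leaf itself. The transcript of STZ, a zinc finger transcription factor of abiotic stress responses, rose by the most among named genes, from 5.25 ± 0.24 in control to 12.04 ± 0.10 in local leaves (SD, n = 2 each), a log2 difference of 6.79 ± 0.35 (SE, adjusted p = 1.8e-05 by limma). ORA47, an AP2/ERF transcription factor that activates jasmonate biosynthesis genes, rose from 5.61 ± 0.23 to 12.28 ± 0.10, a difference of 6.67 ± 0.36 (adjusted p = 2.2e-05). The gene at AT4G29780 rose by 6.64 ± 0.27 (adjusted p = 8.1e-06), and the genes at AT4G27654, AT4G27657 and AT4G27652, which are adjacent in the TAIR10.1 annotation, rose by 6.48, 6.13 and 5.85. CML38, a calmodulin-like calcium-binding protein, rose by 5.59 ± 0.19 (adjusted p = 5.3e-06). The differences of the other 8 of the 15 largest rises lay between 5.40 for AT1G15010 and 5.94 for AT3G02840. They included AT1G33760 and AT1G19210, which encode transcription factors of the AP2/ERF family, at 5.73 and 5.62, and AT5G52050, which encodes a MATE family transporter, at 5.57.

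**Figure D1:**
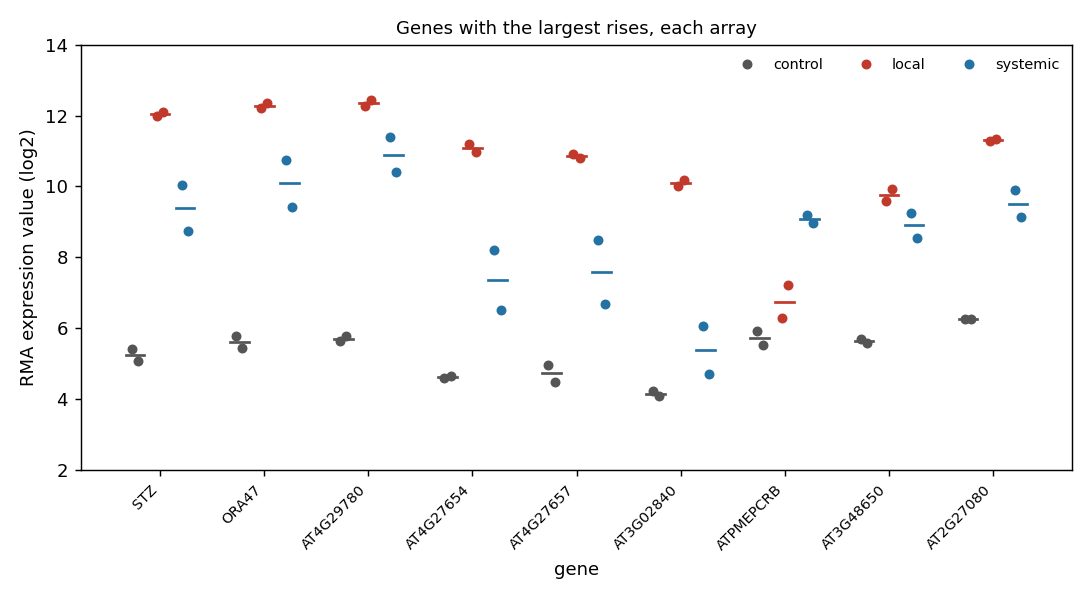
RMA expression value (log2) of the genes with the largest rises, on each array. Points are single arrays (2 control, 2 local, 2 systemic) and short lines are group means. Local values of STZ, ORA47 and AT4G29780 lay at 12.04, 12.28 and 12.35 on average, against 5.25, 5.61 and 5.71 in control, and ATPMEPCRB was higher in systemic leaves (9.08) than in local leaves (6.75).

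Genes of calcium, immune and jasmonate signalling were among those that rose in local leaves. Of the 7 measured members of the list of calcium sensors and pumps, 4 rose, and none fell over all probe sets tested (4 higher and 1 lower adjusted over the list alone). They were CML38, CML37 (3.42 ± 0.10, from a control level near background), CML23 (6.04-fold, log2 SE 0.21) and CML42 (0.94 ± 0.15). The list passed the competitive camera test with the preset correlation (adjusted p = 0.00026), but not with an estimated one (adjusted p = 0.13 with an estimated correlation). Its 7 measured members were all CML genes and no pump was measured, so the test does not cover pumps. Of the 5 measured members of the pattern-triggered and MAP kinase list, 3 rose, both over all probe sets and adjusted over the list alone: the U-box E3 ubiquitin ligases PUB23 (4.79 ± 0.20), PUB22 (3.43 ± 0.19) and PUB24 (0.76 ± 0.16), which are known as negative regulators of pattern-triggered immunity. BIK1, a receptor-like cytoplasmic kinase, differed by 0.12 ± 0.09 (adjusted p = 0.40), and EFR was the other measured member. No MAP kinase of the list was measured, so its test does not cover them and its called members were PUB genes. The camera test of that list gave adjusted p = 0.00074, and the estimated correlation gave adjusted p = 0.23 with an estimated correlation. PUB24 was not past the threshold without control replicate 1 (adjusted p = 0.056).

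Of 3 measured jasmonate biosynthesis genes, 2 rose by either adjustment, including adjusted over the list alone: OPCL1, a CoA ligase of jasmonate precursors, by 2.79 ± 0.22 and JMT, which methylates jasmonic acid, by 1.60 ± 0.11, while the lipase gene DGL differed by 0.08 ± 0.11. The list test gave adjusted p = 0.0015, and adjusted p = 0.13 with an estimated correlation. In the jasmonate response list only ORA47 of 3 measured members rose. PDF1.2, a plant defensin, and THI2.1, a thionin, differed by -0.06 ± 0.13 and -0.02 ± 0.10, and the list was not past the threshold (adjusted p = 0.099, or 0.0495 without local replicate 1). Its median was -0.02 and its mean 2.19. Among the 3 measured members of the WRKY list, WRKY53 rose by 3.09 ± 0.20 and WRKY22 by 3.01 ± 0.23. WRKY6 differed by -0.32 ± 0.17, and by -0.56 without control replicate 2. The list test gave adjusted p = 0.0093, and adjusted p = 0.23 with an estimated correlation. The family of 6 measured genes with the symbol stem WRKY did not pass (2 higher, median -0.07, camera, adjusted p = 0.33). In the auxin response list, the repressor gene IAA29 fell by 1.82 ± 0.24 and GH3.3, which encodes an auxin-conjugating enzyme, fell by 0.67 ± 0.13, with the list not past the threshold (adjusted p = 0.078, or 0.022 and 0.043 without control replicate 1 or 2).

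Other fixed lists had only 1 or 2 measured members and were not tested as lists. XTH18, a xyloglucan endotransglucosylase of the cell wall, rose by 4.23 ± 0.38 and XTH19 differed by 0.12 ± 0.31. The clock gene GI rose by 1.43 ± 0.16 and the dehydrin gene COR47 by 0.60 ± 0.10, while COR15A differed by -0.25 ± 0.12. Of the photosynthesis genes, which stood for mesophyll, LHCB4.1 and RCA differed by -0.06 ± 0.09 and 0.03 ± 0.09. The glutamate receptor-like channel genes GLR3.3 and GLR3.6 differed by 0.20 ± 0.12 and -0.08 ± 0.10, and the glutathione transferase gene GSTU25 by -0.18 ± 0.12. DFR, an enzyme of anthocyanin synthesis, fell by 1.89 ± 0.48 (adjusted p = 0.024) from control arrays that themselves had an SD of 1.31, and it was not past the threshold without local replicate 1 (adjusted p = 0.094) or without local replicate 2 (adjusted p = 0.10), or with robust variance moderation (adjusted p = 0.14); without control replicate 2 its difference was -0.97. Among cell type markers, the phloem sucrose transporter gene SWEET11 was higher by 0.79 ± 0.16 and the dividing cell marker AUR1 fell by 0.89 ± 0.10. The guard cell marker FMA and the trichome marker TRY differed by -0.29 ± 0.17 and 0.34 ± 0.14. Without local replicate 2 the call of SWEET11 was lost (adjusted p = 0.059), and without control replicate 1 FMA passed (-0.53, adjusted p = 0.048).

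The deepest fall among named genes in local leaves was that of AT4G29020, which fell by 5.46 ± 0.28, from 11.96 ± 0.12 in control to 6.51 ± 0.66 in local leaves (SD, n = 2 each, adjusted p = 1.8e-05). AT2G33850 fell by 5.19 ± 0.21, from 9.07 ± 0.48 to 3.88 ± 0.09 (adjusted p = 8.5e-06). AT5G45670, which encodes a GDSL-type lipase, fell by 3.99 ± 0.23, and PYK10, a beta-glucosidase stored in endoplasmic reticulum bodies, fell by 3.25 ± 0.23. The remaining 6 of the 10 largest falls were those of AT1G78170, AT3G15630, AT3G05600, AT5G55450, AT4G29030 and P1R1, which differed by -3.29, -3.11, -3.07, -2.99, -2.71 and -2.58. Final levels near 4, as in AT2G33850, AT5G45670, PYK10 and AT3G05600, lay below the lower quartile of all probe sets (4.41 on both local arrays), where RMA values cannot be told from background and differences are compressed. So did the control levels of AT3G02840, AT1G33760 and AT3G01830 among the largest rises, the levels of THI2.1 and GSTU25 in control and local leaves, and that of GH3.3 in local leaves (4.17).

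In all, 2257 probe sets were higher and 3117 lower in local than in control leaves at an adjusted p under 0.05, of 22746 tested, and 748 and 395 of them by at least 2-fold. Of these, 65 were higher by at least 16-fold and 16 lower by at least 8-fold. After cyclic loess normalization 54.8% of the calls were higher, against 42.0% in the values as deposited. Without local replicate 1 the counts were 1437 higher and 1386 lower, and without control replicate 1 the lower count was 2077.

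The comparison of systemic with control leaves addressed the response of leaves that were not wounded themselves. AT4G29780 rose by the most, from 5.71 ± 0.08 in control to 10.90 ± 0.69 in systemic leaves (SD, n = 2 each), a difference of 5.19 ± 0.27 (SE, adjusted p = 0.00023 by limma). ORA47 rose by 4.48 ± 0.36 (adjusted p = 0.00067) and STZ by 4.13 ± 0.35 (adjusted p = 0.00077). ATPMEPCRB, a pectin methylesterase of the cell wall, rose by 3.35 ± 0.27 (adjusted p = 0.00067), and AT3G48650 and AT2G27080 rose by 3.28 ± 0.22 and 3.25 ± 0.21. The other 9 of the 15 largest rises were those of AT3G04640, AT5G52050, AT1G32920, AT4G27280, AT4G27657, AT3G10930, AT1G66090, AT2G41640 and AT4G27654, between 2.74 and 3.15. The calls of AT4G27657 and AT2G41640 were lost without control replicate 2 (adjusted p = 0.051 and 0.064). With robust variance moderation AT4G27657, AT2G41640, AT3G10930 and AT4G27654 were not past the threshold (adjusted p between 0.056 and 0.13).

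Some members of the same fixed lists also passed in systemic leaves. CML23, CML38 and CML42 rose by 1.63 ± 0.21, 0.97 ± 0.19 and 0.86 ± 0.15, while CML37 stood at 3.85 ± 0.09 against 3.84 ± 0.05 in control, both below the lower quartile of their arrays, where a small change would not be seen. CML41 differed by -0.98 ± 0.31, and by -1.55 without control replicate 2, past the threshold (adjusted p = 0.0023). The calcium list, with 3 of 7 members higher (3 higher and 1 lower adjusted over the list alone), gave adjusted p = 0.024, and adjusted p = 0.21 with an estimated correlation. It was lost without control replicate 2 (adjusted p = 0.14). CML38 lost its call without control replicate 1 or 2 or systemic replicate 1 (adjusted p = 0.0504, 0.0937 and 0.10), and CML42 without control replicate 2 or systemic replicate 1 or 2 (adjusted p = 0.0505, 0.0766 and 0.0557). In the pattern-triggered list PUB23 rose by 1.08 ± 0.20 and PUB24 by 0.93 ± 0.16, and PUB22 differed by 0.57 ± 0.19 (2 of 5 over all probe sets, 3 adjusted over the list alone). PUB23 was not past the threshold without control replicate 1 or 2 (adjusted p = 0.062 and 0.051), nor PUB24 without control replicate 1 or systemic replicate 1 (adjusted p = 0.056 and 0.074). The camera test of that list gave adjusted p = 0.013, and adjusted p = 0.23 with an estimated correlation. By fry, which tests the list against no change, it was not past the threshold either (adjusted p = 0.078).

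OPCL1 rose by 1.42 ± 0.22 and JMT by 0.62 ± 0.11 in systemic leaves, 2 of 3 jasmonate biosynthesis genes measured and 2 adjusted over the list alone (camera, adjusted p = 0.013, and adjusted p = 0.21 with an estimated correlation). JMT was not past the threshold without control replicate 1, systemic replicate 1 or systemic replicate 2 (adjusted p = 0.066, 0.054 and 0.088). The jasmonate response list, where ORA47 alone of 3 members rose, gave adjusted p = 0.024, adjusted p = 0.23 with an estimated correlation, and adjusted p = 0.077 without control replicate 1. PDF1.2 and THI2.1 were at 5.24 ± 0.14 and 4.43 ± 0.10, against 5.24 ± 0.14 and 4.31 ± 0.10 in control. WRKY53 and WRKY22 rose by 2.42 ± 0.20 and 1.84 ± 0.23 (camera, adjusted p = 0.013, and adjusted p = 0.23 with an estimated correlation). The family with the symbol stem WRKY did not pass, with 2 of 6 members higher (camera, adjusted p = 0.063). In the family of 7 measured genes with the symbol stem IAA, 1 was higher and 1 lower (camera, adjusted p = 0.75). IAA29 fell by 1.21 ± 0.24 and GH3.3 fell by 0.73 ± 0.13, 2 of 3 auxin response genes (camera, adjusted p = 0.013, adjusted p = 0.21 with an estimated correlation, and adjusted p = 0.14 with probe sets below the 25th percentile left out). Both were not past the threshold without systemic replicate 1 (adjusted p = 0.12 for IAA29 and 0.055 for GH3.3) or without systemic replicate 2 (adjusted p = 0.058 and 0.072), and IAA29 differed by -0.79 without control replicate 2. XTH18 at 1.34 ± 0.38 and GI at 0.54 ± 0.16 did not pass (adjusted p = 0.075 and 0.079), but XTH18, at 6.59 and 5.13 on the 2 systemic arrays, did without systemic replicate 1 (0.61, adjusted p = 0.044) or 2 (2.07, adjusted p = 0.00023). DFR differed by -1.73 ± 0.48 (adjusted p = 0.068), and passed with differing values without control replicate 1 (-2.66, adjusted p = 0.00052) or 2 (-0.81, adjusted p = 0.014). The dividing cell marker AUR1 fell by 0.67 ± 0.10, and SWEET11, FMA and TRY differed by 0.31 ± 0.16, 0.15 ± 0.17 and 0.46 ± 0.14 without passing. With the replicate number as a block GI, DFR and TRY passed in systemic leaves (adjusted p = 0.033, 0.046 and 0.043), and DFR also with trended moderation (adjusted p = 0.047).

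The largest fall in systemic leaves was that of AT2G33850, which fell by 5.19 ± 0.21, to 3.89 ± 0.26. PYK10 fell by 3.08 ± 0.23 and NAI2, another protein of the endoplasmic reticulum bodies, fell by 1.97 ± 0.18. AT4G29030, AT3G05600 and AT5G33370, the last of which encodes a GDSL-type lipase, differed by -2.91, -2.89 and -2.59. AT3G62550 fell by 2.21 ± 0.37, a call lost without systemic replicate 1 (adjusted p = 0.069). AT1G06100 and AT2G39400 fell as well, with differences of -1.94 and -1.86. ALDH7B4, an aldehyde dehydrogenase, fell by 1.72 ± 0.38 (adjusted p = 0.030), and this call was lost without local replicate 1 or 2 (adjusted p = 0.054 each) and without systemic replicate 1 or 2 (adjusted p = 0.15 and 0.10), while without control replicate 1 its difference was -1.01. Both AT3G62550 and ALDH7B4 also lost it with robust variance moderation (adjusted p = 0.067 and 0.13).

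**Figure D2:**
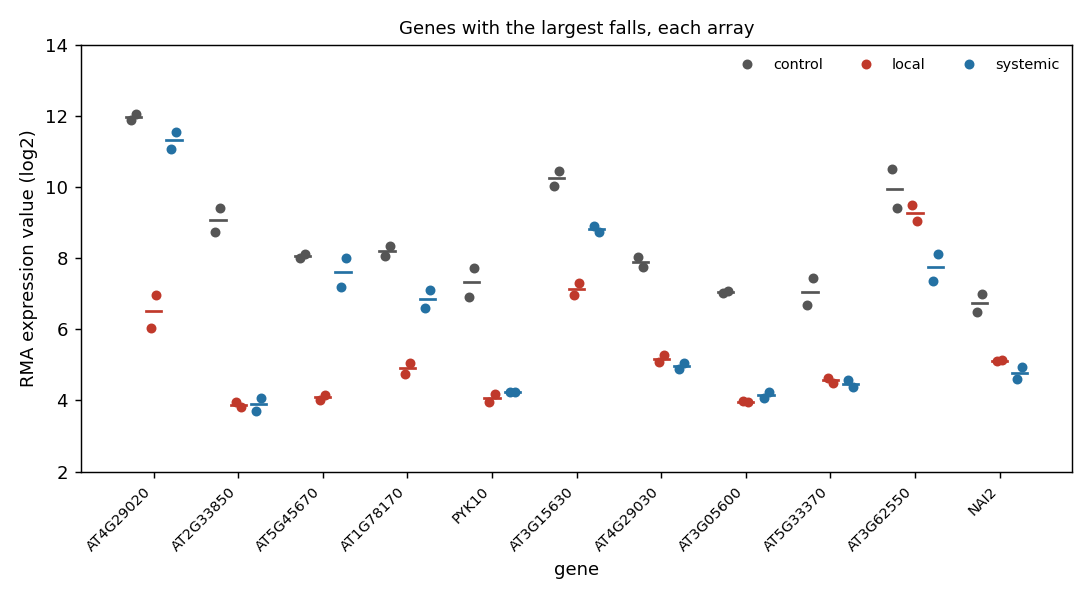
RMA expression value (log2) of the genes with the largest falls, on each array. Points are single arrays (2 control, 2 local, 2 systemic) and short lines are group means. AT2G33850, PYK10 and AT3G05600 were low in both local and systemic leaves, while AT4G29020 and AT5G45670 were low in local leaves (6.51 and 4.08) and near the control level in systemic leaves (11.31 and 7.60).

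In systemic leaves 1076 probe sets were higher and 835 lower than in control, 309 and 140 of them by at least 2-fold. The counts were 537 and 250 without systemic replicate 1, 687 and 394 without systemic replicate 2, 687 higher without control replicate 2, and 432 lower without control replicate 1. The systemic arrays also differed in strength: among 128 probe sets that rose by at least 3 (log2) in local leaves, systemic replicate 1 lay above systemic replicate 2 in 122, with a median difference of 0.81, against -0.01 over all probe sets.

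Many probe sets were called in both comparisons with control. Of the systemic calls, 880 probe sets were higher and 672 lower in both leaves of wounded plants. With unchanged groups simulated against the same control arrays, at most 2 and 1 probe sets were called higher or lower in both over 100 simulations, and independent lists of these lengths would share 106.8 and 114.4. The differences from control correlated across probe sets at r = 0.771, against 0.501 in the simulations, and their covariance was 0.157 against 0.00800 simulated; genes are not independent replicates. With local leaves compared with control replicate 1 alone and systemic leaves with control replicate 2 alone, 642 were higher and 309 lower in both (covariance 0.147), and the other way round 557 and 369 (covariance 0.138), a comparison added after seeing the data. The simulated groups held no changed probe sets, so their counts do not measure what shared controls add to lists of this length. Part of the excess in the counts with both control arrays may come from the shared controls. Without systemic replicate 1 the shared counts were 490 higher and 211 lower, and the shared lower count was 341 without control replicate 1, 434 and 439 without local replicate 1 or 2, and 333 without systemic replicate 2. Among probe sets higher in both, 689 of 880 had the larger value in local leaves, 326 of them past the threshold, and among those lower in both 460 of 672 had the lower value in local leaves, 100 of them past the threshold.

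**Figure D3:**
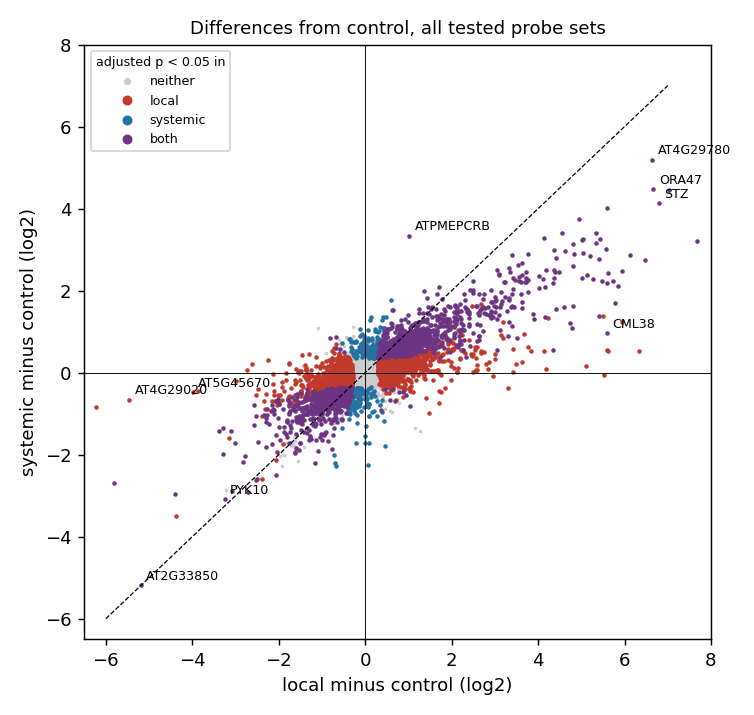
Log2 difference from control in local leaves (x axis) and in systemic leaves (y axis) for all 22746 tested probe sets, coloured by the comparison in which the adjusted p was under 0.05, with the dashed line marking equal differences. Both axes use the same control arrays. STZ lay at 6.79 and 4.13, CML38 at 5.59 and 0.97, ATPMEPCRB at 1.02 and 3.35, and AT2G33850 at -5.19 on both axes.

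The direct comparison of local with systemic leaves of wounded plants addressed what set the wounded leaf apart from unwounded leaves of wounded plants. The groups are different leaves, so any difference in leaf age or position, which was not examined, cannot be told apart from wounding here. AT1G19210 was higher in local leaves by 5.08 ± 0.26 (10.15 ± 0.26 against 5.06 ± 0.65, SD, n = 2 each, adjusted p = 7.6e-05 by limma). AT3G02840 was higher by 4.71 ± 0.35, CML38 by 4.62 ± 0.19 and the U-box ligase gene PUB19 by 3.79 ± 0.12. AT3G01830, AT5G38700, AT5G17350 and AT1G15010 were higher by between 4.02 and 4.12, AT5G38700 against a systemic level near background (4.02). AT4G29020 was lower in local leaves, at -4.80 ± 0.28, as were the lipase gene AT5G45670 at -3.51 ± 0.23 and AT5G55450, which encodes a lipid transfer protein, at -2.79 ± 0.18. The differences of AT1G11850, AT5G02890, NANA and AT1G78170 were -2.56, -2.09, -2.01 and -1.95. ATPMEPCRB was lower in local than in systemic leaves, at -2.33 ± 0.27 (adjusted p = 0.0025), while its difference between local and control leaves was 1.02.

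By list, the calcium sensors had 3 of 7 members higher in local than in systemic leaves by either adjustment, including adjusted over the list alone: CML37 (3.41 ± 0.10, against a systemic level near background), CML38 and CML23 (0.96 ± 0.21). The camera test gave adjusted p = 0.00017, and adjusted p = 0.13 with an estimated correlation. CML23 was not past the threshold without local replicate 1 or 2 (adjusted p = 0.17 and 0.082) or systemic replicate 2 (adjusted p = 0.15). PUB23 and PUB22 were higher by 3.71 ± 0.20 and 2.86 ± 0.19, 2 of 5 members of the pattern-triggered list and 2 adjusted over the list alone (camera, adjusted p = 0.0058, and adjusted p = 0.44 with an estimated correlation). OPCL1 and JMT were higher by 1.37 ± 0.22 and 0.98 ± 0.11, 2 of 3 jasmonate biosynthesis genes (camera, adjusted p = 0.0024, and adjusted p = 0.13 with an estimated correlation), OPCL1 not without local replicate 1 (adjusted p = 0.073). XTH18, STZ and ORA47 were higher by 2.89 ± 0.38, 2.66 ± 0.35 and 2.19 ± 0.36, and ORA47 was not past the threshold without local replicate 1 (adjusted p = 0.069) or with robust variance moderation (adjusted p = 0.059). WRKY22 was higher by 1.17 ± 0.23, but not without local replicate 2, systemic replicate 1 or systemic replicate 2 (adjusted p = 0.084, 0.051 and 0.13), and the WRKY list did not pass (adjusted p = 0.059, or 0.036 without either control array and 0.0073 without local replicate 1). COR47 and GI were higher by 0.85 ± 0.10 and 0.90 ± 0.16, GI not without local replicate 1 or systemic replicate 2 (adjusted p = 0.081 and 0.085). The jasmonate response and auxin lists were not past the threshold (adjusted p = 0.44 and 0.89).

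In this comparison 1084 probe sets were higher and 1122 lower in local than in systemic leaves, 368 and 158 of them by at least 2-fold, and cyclic loess normalization moved the higher share of calls from 49.1% to 60.5%. The counts fell to 358 and 200 without local replicate 1, 666 and 520 without systemic replicate 1, and 512 and 268 without systemic replicate 2.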

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

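The tests of mixing, shared controls and organelle transcripts, and those of the symbol families, were chosen after the results had been seen; the tests of the fixed lists were planned. Groups of 2 arrays are too small for a rule on outlying samples; control replicate 2 had the lowest spike means (7.40 for poly-A and 9.41 for hybridization).

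Local and systemic leaves differed in direction against the same control for 14 probe sets, which were called higher in one and lower in the other. Each had a local minus systemic difference past the threshold. That follows from choosing calls of opposite sign with a shared standard error, so it is no separate test. Independent lists of these lengths would hold 230.3 opposite calls. Both comparisons use the same control arrays, which favours calls in the same direction. Differences of unchanged groups simulated against these arrays already correlated at r = 0.501. The figure for independent lists therefore cannot show whether opposite calls were rarer than the design alone would give. Chosen after their values were seen, the 5 of them with 1 listed gene were APS4, AT4G09760 and AT1G21000, higher in local (0.78, 0.57 and 0.95) and lower in systemic leaves (-0.48, -0.67 and -0.55), and AT1G52770 and AT1G11330, lower in local (-0.49 and -0.68) and higher in systemic leaves (0.51 and 0.61).

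A larger set of 106 probe sets was higher in systemic leaves than in both control and local leaves. In 89 of them local leaves were not past the threshold against control. Their number fell to 62 and 61 without control replicate 1 or 2, 31 without local replicate 1, and 33 and 32 without systemic replicate 1 or 2. Chosen after their values were seen, examples besides ATPMEPCRB were AT1G23205 (1.76 ± 0.20 in systemic against control), the beta-expansin gene EXPB1 (1.35 ± 0.24) and the pectate lyase gene AT1G67750 (1.06 ± 0.22). Their local differences were 0.59 ± 0.20, 0.14 ± 0.24 and -0.12 ± 0.22. The 2 local arrays disagreed in these genes (SD 0.46, 0.63 and 0.55) and in ATPMEPCRB (SD 0.65), against a median SD of 0.0770. Their local levels are therefore uncertain. Whether leaf age or position differed between the groups was not examined either.

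Systemic rises that follow local rises could come from wounded-leaf material mixed into the systemic pools. One share of local material per array would then set the systemic value of each gene, but 57.0% of the 128 probe sets that rose by at least 3 in local leaves lay over 0.5 (log2) from the value of that array's median share on systemic replicate 1, and 59.4% on systemic replicate 2. The implied share ran from 4.79% at the 10th to 55.3% at the 90th percentile on replicate 1. On replicate 2 it ran from 1.40% to 32.1%. Shares take RMA values as proportional to amount, while dim values are compressed, which can widen this spread. Mixing also cannot produce the 106 probe sets above local leaves (at most 4 in 20 simulated mixtures, which were held between control and local values). Of these 106, 89 were not past the threshold in local leaves, so they bear little on the rises shared with local leaves. The simulated unchanged groups hold no changed probe sets, so their at most 2 shared calls do not measure what shared control arrays add to the 880. When each comparison had its own control array, the covariance of the differences was 0.147 and 0.138, against 0.157 with shared ones. Chance values of the shared control arrays alone therefore do not account for the likeness of the 2 comparisons. A small admixture beside a response of the systemic leaf remains open, as does handling of the wounded plants, which was not tested; a signal that reaches unwounded leaves within 10 min is therefore a hypothesis.

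By a test of the local minus systemic difference, 3 fixed lists and 6 symbol families stood apart, all upward in local leaves except those named PRA and GH, and none with an estimated correlation (adjusted p between 0.13 and 0.54). The lists were calcium sensors (adjusted p = 0.00017), jasmonate biosynthesis (adjusted p = 0.0024) and the pattern-triggered list (adjusted p = 0.0058). The calmodulin-like (CML) family gave adjusted p = 0.0016, with members largely shared with the calcium list, and the U-box ligases (PUB) adjusted p = 0.0093. The glutamate receptor-like (GLR) family gave adjusted p = 0.045, with GLR2.7 the only member of 7 past the threshold (1.16), and lost its call without local replicate 1 or 2 or systemic replicate 1 (adjusted p = 0.079, 0.053 and 0.083). Families with the symbol stems PRA and GH were lower (adjusted p = 0.028 and 0.047), and both lost their call with probe sets below the 25th percentile left out (adjusted p = 0.085 and 0.15), without local replicate 1 (adjusted p = 0.11 each), and without systemic replicate 1 (adjusted p = 0.058 and 0.083), and GH also without systemic replicate 2 (adjusted p = 0.053); fry, which tests against no change, gave adjusted p = 0.10 and 0.088.

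The family of 11 mitochondrion-encoded genes shifted upward in local against systemic leaves (camera, adjusted p = 8.6e-05, and adjusted p = 0.54 with an estimated correlation): 5 genes passed, among them nad4L at 1.09 ± 0.10 and cox1 at 0.89 ± 0.12, 4 were higher by value, nad7 and nad2 differed by -0.13 and -0.30, and the median was 0.50. A single array standing apart is not enough, since the median was 0.27 or higher whichever array was left out. A greater recovery of organelle transcripts in general from wounded leaves would raise plastid transcripts as well, but the median of 69 plastid-encoded genes was -0.0375, 0.54 below that of the mitochondrion-encoded genes, with an SD of 0.24 among the plastid-encoded genes, the highest of which was at 0.37. A change in the signals of mitochondrion-encoded genes in wounded leaves may therefore be worth following, as a hypothesis. It remains open whether probes that also match nuclear copies of mitochondrial genes, or RNA quality take part. The same holds for how the 3' amplification labels mitochondrial transcripts, so the signals may not follow transcript amounts. None of these was tested. The ubiquitin 3' minus 5' difference was lowest on the local arrays (0.97 and 1.05).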

How the results depend on the processing

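The values without single arrays and those under cyclic loess, the block and the filters were planned; the families' alternatives, the separate control arrays and the counts above local leaves were added after seeing the data. No called value changed sign. Counts of called probe sets stayed within 1.5 times of those reported under median centring, cyclic loess, both filters, trended and robust moderation and the 4-array fits. With probe sets of exactly 1 gene the counts were 1180 higher and 1671 lower (local against control), 577 and 447 (systemic against control), 598 and 639 (local against systemic), 463 higher in both and 356 lower in both, because fewer probe sets were tested. Leaving out 1 array gave between 1437 and 2147 higher and 1386 and 2893 lower in local against control, 537 and 935 higher and 250 and 732 lower in systemic against control, 358 and 1175 higher and 200 and 1154 lower in local against systemic, and 490 to 724 higher and 211 to 577 lower in both; the cause of these shifts was not tested. With each comparison given its own control array, 642 and 557 were higher and 309 and 369 lower in both. With an estimated correlation 0 of the 4, 6 and 3 lists called in local against control, systemic against control and local against systemic passed. That correlation was below the preset 0.01 for the calcium, jasmonate biosynthesis and auxin lists (-0.075, -0.126 and -0.338). It was above it for the pattern-triggered, jasmonate response and WRKY lists (0.72, 0.65 and 0.84). In the first 3 lists the loss goes with the few degrees of freedom of that test, not with correlated members. In the 3 comparisons 7852, 5049 and 5297 single probe sets had an unadjusted p under 0.05 by limma, and fry called 6, 5 and 3 lists.

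The labels do not state whether shared replicate numbers mark a batch, or whether local and systemic pools came from the same plants. The replicate deviations correlated at 0.137 between control and local, 0.0213 between control and systemic and 0.199 between local and systemic. On the second principal component (15.1% of the variance) replicates 1 and 2 lay at -16.7 and -7.54 in control leaves. They lay at -15.0 and -5.51 in local and at 21.8 and 23.1 in systemic leaves. Replicate 2 was thus higher in each group, and a shared replicate effect or a pairing stays open. With the number as a replicate block the counts rose to 2373 higher and 3329 lower, 1209 and 998, and 1243 and 1303 in the 3 comparisons. Of the 66 largest rises and falls, 66 kept their call under the block and cyclic loess, 60 under robust moderation, and 64 or more without any single array. Of the 102 values of list members, 97 kept their side of the threshold under the block and 5 that had not passed did. Tests of upstream motifs and gene structure were not run. Falls that end near background, as that of AT2G33850, are limited in size. Others, as that of AT4G29020 in local leaves, ended above it.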

Other observations

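The family tests and the tests of the deep falls were chosen after the data had been seen; the neighbour test was written down before its value was known.

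Families of genes that share a symbol stem were tested beside the fixed lists. In local leaves 4 of 5 measured beta-tubulin genes fell against control (TUB1 at -1.19, TUB7 at -0.92, TUB5 at -0.63 and TUB6 at -0.53). Camera gave adjusted p = 0.0071, and adjusted p = 0.49 with an estimated correlation. In systemic leaves all 5 were lower by value (median -0.25), 1 of them past the threshold. There camera gave adjusted p = 0.051, and 0.62 with an estimated correlation. It passed with the replicate block, median centring and cyclic loess (camera, adjusted p = 0.028, 0.048 and 0.042). U-box ligase genes, of which PUB22, PUB23 and PUB24 also belong to the pattern-triggered list, rose in both leaves: 6 of 9 in local leaves, led by PUB23 and PUB19 (4.34), and 5 of 9 in systemic leaves, among them PUB25 (1.16) and PUB26 (0.95). The camera test gave adjusted p = 7.9e-05 and 0.00029, and adjusted p = 0.43 and 0.45 with an estimated correlation; fry, which tests against no change, gave adjusted p = 0.055 in systemic leaves. In systemic leaves the autophagy (ATG) family shifted down, with 2 of 8 members past the threshold (ATG8F at -0.72 and ATG8H at -0.38). Camera gave adjusted p = 0.00029, and adjusted p = 0.45 with an estimated correlation. The median was -0.36 in systemic and -0.35 in local leaves, where 3 of 8 members were lower. The local test did not pass by camera (adjusted p = 0.14) but did by fry (adjusted p = 0.016). In the bZIP family 3 of 14 members rose in systemic leaves, BZIP60 by 0.77, BZIP34 by 0.73 and BZIP53 by 0.64 (adjusted p = 0.021, and adjusted p = 0.62 with an estimated correlation), a call lost without systemic replicate 1 (adjusted p = 0.15), and fry gave adjusted p = 0.061. BZIP60, a transcription factor of the unfolded protein response, rose by 1.35 in local leaves. Against control, the mitochondrion-encoded genes passed in local leaves (adjusted p = 0.0024, and adjusted p = 0.43 with an estimated correlation; 5 of 11 higher). The plastid-encoded genes passed in systemic leaves with 1 of 69 members higher (adjusted p = 0.047, and adjusted p = 0.84 with an estimated correlation), fry gave adjusted p = 0.66, and the call was lost with cyclic loess (adjusted p = 0.30), with the dimmest probe sets left out (adjusted p = 0.091) and without control replicate 2 or systemic replicate 1 (adjusted p = 0.66 and 0.99).

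Deep falls within 10 min stand out because a transcript cannot fall faster than it decays. If synthesis had stopped at wounding, the fall of 5.46 in AT4G29020 needs a half-life of at most 1.83 min, and the fall of AT2G33850 one of at most 1.93 min in both leaves. Of the 16 probe sets at least 4-fold lower in systemic leaves than in control, 12 were also lower in local leaves. A single high control array could give such means: of the 24 probe sets with a systemic mean at least 4-fold lower than control, 8 were not called, and in all 8 control replicate 1 lay above control replicate 2, by 2.27 or more (log2); over the 24, the lower control array lay above the highest of the 4 arrays of wounded plants by a median of 0.91. Among the 16 called that median was 1.98, but their choice by a called fall favours such a gap, so this value does not settle how far a high control array took part in them. A difference between unwounded and wounded plants that was there before wounding, and equal in both leaves, would leave local and systemic leaves alike. They differed by a median of 0.69 over the 16. In the 8 with a systemic mean of at least 5 the median was 1.36, and 6 differences passed the threshold (4 higher and 2 lower in local leaves). In these 8 as a set an equal prior difference alone does not give the levels of both leaves. Together with a further change in 1 of the leaves it stays open. So does a prior difference that varied between leaves, since it is not stated whether both pools came from the same plants. Choosing the 16 by their systemic fall also favours higher local values. In the other 8, with systemic means under 5, a prior difference cannot be told apart from an effect of wounding: the median difference was 0.18, where the floor of the array can hide differences, and control and wounded plants are distinct. AT2G33850 is among these 8, so its half-life holds only if its level fell after wounding.

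Among the genes named here, which cover 52.5% of the probe sets called in local leaves, those that changed in local leaves lay next to each other more often than chance gave. Among 5229 pairs of adjacent genes that were both measured, 69 pairs were both higher in local leaves, against 39.8 on average and 65 at most in 10000 permutations of the calls over genes (one-sided, p = 0.0001, the smallest they can give; adjusted p = 0.0004 over 4 tests). Pairs lower in local leaves numbered 113, against 78.2 (adjusted p = 0.0004), pairs higher in systemic leaves 15, against 8.72 (adjusted p = 0.042), and pairs lower in systemic leaves 2, against 5.09 (adjusted p = 0.96). Besides AT4G27652, AT4G27654 and AT4G27657, the pairs AT5G52750 and AT5G52760 (2.50 and 2.50) and AT3G48640 and AT3G48650 (2.30 and 4.13) rose together in local leaves. Neighbours that are tandem copies could share probe signal, which was not tested, so clustering of the named genes along the chromosomes is a hypothesis that these counts allow.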
